A study of Caenorhabditis elegans with 2 samples.

How the data were processed

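The material was chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole *Caenorhabditis elegans*. The animals came from a strain with an integrated transgene that expresses LSY-12 fused at its C terminus to GFP and FLAG, and an antibody against GFP was used, per the labels. LSY-12 is a histone acetyltransferase of the MYST family, and *lsy-12* is known as a gene needed for the left-right difference between the ASE taste neurons. Both samples were of mixed sex and were collected at the L3 larval stage, 43 h after synchronization as starved L1 larvae. The chromatin was sheared by sonication. Both samples belong to 1 group and are biological replicates with the numbers 3 and 4 in the labels. The labels name no second condition, and the control library named there was not analysed here.

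The deposited lists are peak calls in narrowPeak form without a header line. Per the deposited text descriptions, the authors called candidate regions and background on the alignments of each replicate with a control alignment. They made a pooled list in the same way from both replicates, and a thresholded list by the irreproducible discovery rate (IDR) procedure from the replicate lists and the pooled list. Each list was deposited for the genome builds ce10 and ce11. The aligner and the peak caller are not given in the sources used here. The signal value that the authors gave each region has no stated scale, and it was used only to rank, filter and describe regions within a list. The deposited −log10 q-value of each region was used only to count regions. The deposited offset of the summit from the region start, another column of the same lists, set the summit positions. The summit lay at the middle of the region for 99.5% of the replicate 3 regions and 90.1% of the thresholded peaks. A summit here is thus mostly a region's midpoint. Read counts and sequencing depth are not given in these lists, so the precision of a single region is known only from the spread between the replicates. All intervals on shares of regions or genes are exact Clopper-Pearson 95% intervals and cover counting error only.

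All positions refer to ce11 (WBcel235) and count from 1. No region extended past the end of a WBcel235 chromosome. The ce10 lists were used only for the overlap of the replicates and for numbers of peaks per chromosome, and no position was carried between builds. Genes came from the Ensembl release 115 annotation of the nuclear chromosomes, which held 19973 protein-coding genes. A gene was called bound when a thresholded summit lay within 500 bp of its most 5' annotated start. The relative signal of a region is its signal divided by the median signal of the 30000 regions of the same list. Relative signals are given as mean ± SD over the 2 replicates, each taken from the replicate region that overlapped the thresholded region. For genes that were not bound, each replicate gave its strongest candidate region with a summit in the window. Those regions can differ between the replicates.

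Replicates were compared by the share of the 2095 regions of highest signal in one list that overlapped such a region of the other by at least 1 bp. This share was set against 1000 circular shifts of the list along each chromosome in a one-sided permutation test, and 200 shifts were used for its alternatives. The position of summits was set against 1000 circular shifts in a two-sided permutation test. The 20 gene lists, the 7 non-coding gene classes and the chromosomes were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family of tests. These tests count genes as independent, although neighbouring genes can share a summit. Hexamers, with both strands collapsed, were counted in the 101 bp around each summit and in windows of that length 300 bp to either side, and compared with two-sided Fisher's exact tests. The gene lists, the tests, the windows and most alternatives were chosen before the data were examined. The alternatives were a stricter peak threshold, other overlap rules, other promoter windows, assignment to the nearest start within 5000 bp, other backgrounds, circular shifts of the bound state along gene order, and each replicate alone. Chosen after the data were seen were a background restricted to mostly single-copy windows, genome windows matched in GC content outside the pooled candidate regions, and the histone acetylation list without *lsy-12*. A window was called mostly single-copy when at most 10% of its 32-mers occurred more than once in the reference, on either strand.

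The genes named were fixed by rule. They were *lsy-12* and the members of the ASE list, the genes at the 15 thresholded peaks of highest signal, the 4 bound members of highest signal in each list past an adjusted p of 0.05, and the 2 of highest signal in each other list. The 5 hexamers with the smallest adjusted p in each direction were also named. The homeobox list lost 1 member with no match in the annotation.

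The procedures were tested on simulated data. For the gene lists, over the 19973 genes, 85.5% of lists given 6-fold odds were called and 0.982% of unchanged lists were called higher. Each gene's bound state was drawn independently there, so these rates do not cover lists whose members share a summit. For replicate overlap, in simulated lists of 2095 regions with 41.1% shared by construction, 44.1% were found to be shared. A hexamer planted in 20.0% of 2095 shifted windows ranked 1 among the summit hexamers. With it, 24 other hexamers were called, of which 3 shared no 4 consecutive bases with the planted one, so calls on hexamers other than the strongest are less certain. With none planted, 0 were called at the 2095 shifted places. These places were not matched to the GC content of summits (median 47.5%, against 34.7% in the flanks). The 0 thus does not cover calls that arise from base composition at real summits. For the genomic distribution, 5.0% of 40 shifted lists of 2095 peaks had a promoter p under 0.05. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.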

Results

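Binding of LSY-12, a histone acetyltransferase of the MYST family needed for the left-right difference between the ASE taste neurons, was measured by ChIP-seq with an antibody against GFP in whole L3 larvae that carried a tagged copy of the protein. A single group was measured, with 2 biological replicates, numbered 3 and 4. Each replicate list and the pooled list held 30000 candidate regions, and the thresholded list, made by the authors from both replicates, held 2095 peaks with a median width of 410 bp. Of the candidate regions, 942 (3.14%) in replicate 3 and 1317 (4.39%) in replicate 4 had a q-value of 0.01 or below in the authors' lists. Of the 2095 thresholded peaks, 1222 (58.3%) did. Each thresholded peak was among the 2095 pooled regions of highest signal. Read depth is unknown from these lists, and no animals without the tagged protein were analysed here, so signal that does not depend on LSY-12 was not measured.

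The strongest LSY-12 regions of one replicate were mostly among the strongest of the other, and lower-ranked ones less often. Of the 100 strongest regions of replicate 3, 99 (95% lower bound 94.6%) overlapped one of the 2095 strongest of replicate 4. Of those ranked 1001 to 2095, 51.6% (48.6 to 54.6%) did so. Part of this fall is built in, since regions ranked near the cut of 2095 drop out with small changes of rank. Of the 2095 thresholded peaks, 2091 were overlapped by a candidate region of both replicates. The peaks were made from these same replicates, and the lists of 30000 regions include background, so this count says little about replication. Among the 2095 strongest regions of each replicate, 1480 thresholded peaks (70.6%) overlapped one in both, and 51 overlapped one in neither. Over all 2095 regions, 1503 (71.7%) of replicate 3 were shared with replicate 4, against a mean of 1.69% and a highest value of 3.10% after circular shifts of the regions (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). In the other direction, 1478 (70.5%) were shared. The signal of overlapping regions correlated with Spearman's rho = 0.722 across these regions, which are not independent replicates. No shifts were run over all 30000 candidate regions, so the share there cannot be read like the 71.7%. Of those of replicate 3, 59.1% overlapped a candidate region of replicate 4, with rho = 0.461. The plot of both replicates' signal shows this relation for thresholded peaks.

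**Figure D1:**
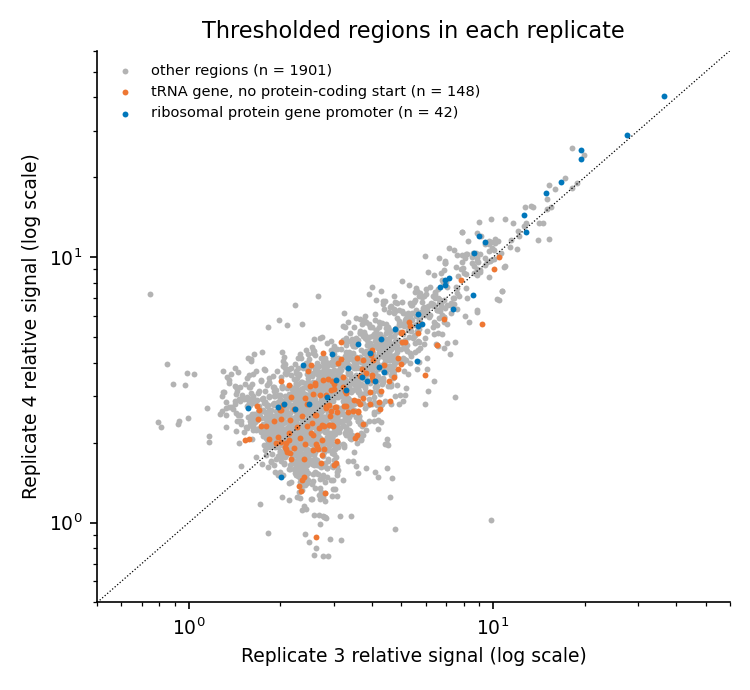
Relative signal (signal divided by the median of the list, log axes) in replicate 3 and replicate 4 for the 2091 thresholded peaks overlapped by a region of both. Colours mark 42 promoter peaks of ribosomal protein genes and 148 peaks near a tRNA gene with no protein-coding start within 500 bp.

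LSY-12 peaks lay at promoters more often, and in coding exons and introns less often, than shifted positions. Of the 2095 summits, 846 (40.4%, 95% interval 38.3 to 42.5%) lay within 500 bp of a protein-coding start, against a mean of 18.4% after shifts, a 2.20-fold difference. Coding exons held 91 summits (4.34%, against 19.3%) and introns 451 (21.5%, against 29.5%). Each of these 3 differences had an adjusted p of 0.00333 (two-sided permutation, raw p = 0.002, the smallest that 1000 shifts can give). Untranslated exons (52 summits, 0.752-fold, adjusted p = 0.0599) and sequence between genes (655 summits, 1.06-fold, adjusted p = 0.142) did not pass in the permutation test. In replicate 4 alone the value for untranslated exons was 1.08-fold, and with a window of 1000 bp upstream and 100 bp downstream that for sequence between genes was 0.960-fold. Untranslated exons passed with every annotated transcript start (0.574-fold) and with the peaks of above-median signal (0.579-fold), and coding exons had 0.103-fold with the latter. Within 500 bp of a start, 704 summits lay upstream and 142 at or downstream of it, with a median position of −160 bp. A further 651 summits (31.1%) lay more than 2000 bp from any protein-coding start.

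**Figure D2:**
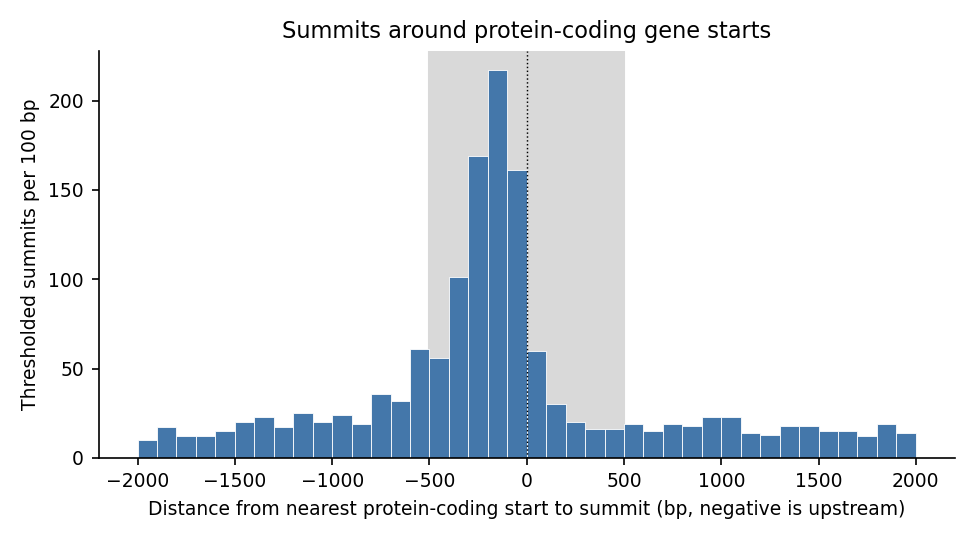
Number of thresholded summits in bins of 100 bp by signed distance (bp) to the nearest protein-coding start, with the promoter window of 500 bp on either side in grey. Most summits inside the window lie upstream, with a median at −160 bp.

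Promoters of ribosomal protein genes were prominent among the strongest LSY-12 peaks. The highest signal was at −283 bp from the start of *rpl-3* (III:3867402–3867771, ce11), with a relative signal of 38.5 ± 2.83 (SD, n = 2). A peak at IV:4749918–4750241, between the divergent starts of *rpl-20* and *Y17G9B.5*, followed with 28.2 ± 0.829, and a peak shared by *rpl-15* and *K11H12.8* with 22.3 ± 4.15. Next came *tasp-1*, a homolog of the protease taspase (22 ± 3.08), *cdc-48.1*, an AAA ATPase (22 ± 5.33), *rpl-35* (21.5 ± 2.84), *hsp-1*, an Hsp70 chaperone (19 ± 0.188), *vig-1* (18.6 ± 1.87) and *rps-1* (18 ± 1.77). A peak at III:9765460–9765801, at −907 bp from the start of *cbp-1*, the homolog of the acetyltransferases CBP and p300, reached 18.2 ± 0.00722. The remaining peaks of the top 15 were at *C47E8.4* (17 ± 2.51), *cox-5A* (17 ± 1.45), *rps-19* with *hsr-9* (16.2 ± 1.84), *iff-2*, a homolog of translation factor eIF5A (15.8 ± 1.05), and *Y22D7AL.10* (15.5 ± 0.0879). These values have no test, and the order of peaks whose means differ by less than their SD is not resolved.

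In all, 1050 of 19973 protein-coding genes (5.26%) had a summit in the promoter window, and 441 of these (42%) shared it with another gene's window. With the peaks of above-median signal 611 genes were bound, and with the nearest start within 5000 bp 1607. Cytosolic ribosomal protein genes stood out, with 45 of 80 bound (56.3%, against 5.05% of other genes, odds ratio 24.2, 95% interval 15.1 to 38.9, adjusted p = 2.16e-35 by Fisher's exact test). Bound more often were also the genes of translation factors (9 of 30, odds ratio 7.78, adjusted p = 4.44e-05), the proteasome (10 of 33, 7.90, 1.89e-05), oxidative phosphorylation (11 of 40, 6.90, 1.89e-05) and heat shock proteins (6 of 23, 6.39, 0.00216), all by two-sided Fisher's exact tests. Among them were *eef-2* (10.3 ± 1.25), *eif-3.C* (8.98 ± 0.445) and *eef-1A.1* (8.28 ± 2.29) of the translation factors. The proteasome genes included *rpn-3*, whose peak is shared with *hsp-110* (10.6 ± 2.45), *rpn-11* (4.29 ± 1.28), *rpn-5* (3.6 ± 0.757) and *rpt-2* (3.09 ± 1.02). Summits shared with another gene's window made up 8 of the 10 bound proteasome genes (*rpn-5* and *rpt-2* among them), 28 of the 45 ribosomal protein genes, 4 of the 9 translation factor genes, 4 of the 11 genes of oxidative phosphorylation and 4 of the 6 heat shock genes. Those of oxidative phosphorylation included *cox-5B* (14.1 ± 1.95), *atp-1* (11.3 ± 3.21) and *cyc-1* (4.98 ± 0.685), and the heat shock genes *hsp-3* (12.1 ± 0.151) and *hsp-6* (2.82 ± 0.360). With each summit assigned to its nearest start, the odds ratios were 7.35 for ribosomal proteins, 4.92 for translation factors, 4.99 for the proteasome, 4.36 for oxidative phosphorylation and 4.04 for heat shock proteins. Among genes with a pooled candidate region in the window, they were 11.0 for ribosomal proteins, 4.79 for translation factors and 4.92 for the proteasome. With the peaks of above-median signal, translation factors had 13.8, and the proteasome (4.39, adjusted p = 0.0502 by the exact test) and heat shock lists (4.77, 0.0795) no longer passed.

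**Figure D3:**
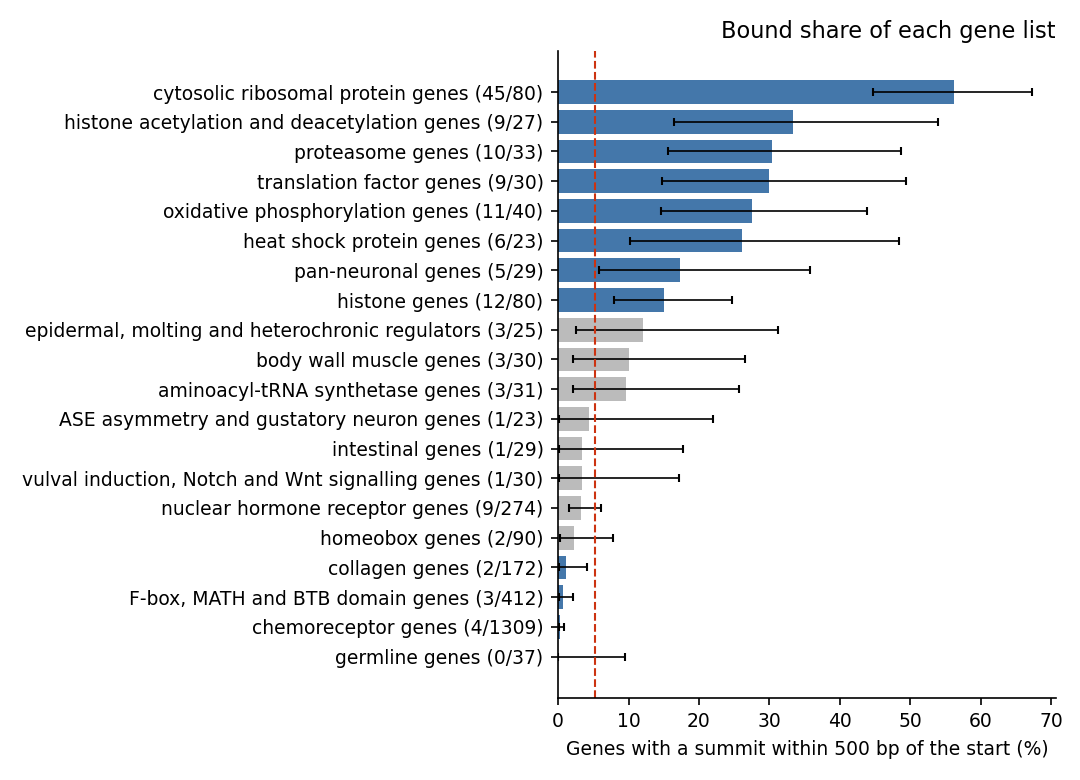
Percent of each gene list with a summit within 500 bp of the start, with exact 95% intervals, for 20 lists. The dashed line marks all protein-coding genes (5.26%), and blue marks lists with an adjusted p under 0.05.

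Genes for histone acetylation and deacetylation, the functional group of LSY-12 itself, were bound more often than others, with 9 of 27 (33.3%, odds ratio 9.08, 95% interval 3.58 to 21.3, adjusted p = 1.96e-05 by Fisher's exact test). The strongest were *lin-53*, a histone-binding protein of the RbAp family (10.4 ± 0.627), *hat-1* (6.71 ± 0.366), *epc-1*, a homolog of Enhancer of Polycomb (6.31 ± 0.864), and *mrg-1*, a chromodomain protein (3.98 ± 0.0577). The summits of *lin-53* and *mrg-1* also lay in the window of another gene. The transgene carries *lsy-12*, and without this gene 8 of 26 were bound (odds ratio 8.06, adjusted p = 0.000108 by the exact test, chosen after the data were seen). With the nearest start the odds ratio was 5.74, where *lin-53*, *mrg-1* and *trr-1* were no longer counted and *bet-1*, *cbp-1* and *hda-4* were, and it was 5.23 among genes with a pooled candidate region. Of these, *trr-1*, *bet-1* and *hda-4* were named after their values were seen. Histone genes were bound in 12 of 80 cases (odds ratio 3.21, adjusted p = 0.00216 by the exact test), with *his-37* (14.5 ± 1.60), the pair *his-67* and *his-68* at 1 summit (5.28 ± 0.424) and the linker histone gene *his-24* (3.88 ± 0.480). Of the 12 bound histone genes, 10 shared the summit with another gene's window. Of the 80 histone gene windows, 63 had over 10% of their 32-mers in more than 1 copy, and among mostly single-copy windows the odds ratio was 7.08. The histone gene list no longer passed with replicate 3 alone (odds ratio 1.85, adjusted p = 0.196 by the exact test), with the peaks of above-median signal (2.58, 0.0795) or with the nearest start (1.27, 0.710).

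Genes of the large chemoreceptor and F-box families were rarely bound. Chemoreceptor genes had 4 of 1309 bound (0.306%, odds ratio 0.0516, adjusted p = 5.25e-25), and genes with F-box, MATH or BTB domains 3 of 412 (0.728%, odds ratio 0.130, adjusted p = 6.14e-06), by two-sided Fisher's exact tests. The bound chemoreceptor genes were *sri-5* (4.62 ± 0.245), *srh-16* (4.33 ± 0.40), *srh-269* (3.49 ± 0.662) and *srh-2* (2.51 ± 0.539), and the bound F-box and MATH genes *fbxb-85* (7.50 ± 1.01), *bath-36* (3.76 ± 0.693) and *fbxb-72* (2.99 ± 1.17). The summit also lay in another gene's window for 3 of these 4 chemoreceptor genes (all but *srh-269*) and for 2 of the 3 F-box and MATH genes (all but *fbxb-72*). Collagen genes, which encode the cuticle, had 2 of 172 bound, *col-38* (4.03 ± 0.265) and *col-85* (2.29 ± 0.186), the former by a summit that also lies in the window of the ribosomal protein gene *rpl-5*, with an odds ratio of 0.211 and an adjusted p of 0.0185 by the exact test. The odds ratio of chemoreceptor genes was 0.150 with the nearest start, and that of F-box, MATH and BTB genes 0.256 with the wider upstream window. The collagen call was lost with replicate 4 alone (0.323, adjusted p = 0.0738), with the peaks of above-median signal (0.184, 0.139), with the wider upstream window (0.356, 0.0672), with the nearest start (0.555, 0.20) and with mostly single-copy windows (0.251, 0.0657), all by exact tests.

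Of the lists for tissues, pan-neuronal genes passed, with 5 of 29 bound (odds ratio 3.77, 95% interval 1.12 to 10.1, adjusted p = 0.0300 by Fisher's exact test). They included *unc-14* (2.81 ± 0.736), *egl-21* (2.52 ± 0.191), *snb-1* (2.48 ± 0.429) and *syd-2* (2.44 ± 0.128). This call did not hold with replicate 4 alone (2.94, adjusted p = 0.110 by the exact test) or with shifts along gene order (3.29-fold, permutation adjusted p = 0.0640), and none of the 29 was bound by the peaks of above-median signal, whereas with the nearest start within 5000 bp 12 were (8.12, exact adjusted p = 4.02e-06). Epidermal, molting and heterochronic regulators had 3 of 25 bound (odds ratio 2.46, adjusted p = 0.236 by the exact test), among them *lin-28* (4.28 ± 0.0437) and *lin-14* (2.72 ± 0.602). With the nearest start this list had 12 of 25 (48.0%, against 8.0% of other genes, odds ratio 10.6, 95% interval 4.42 to 25.3, adjusted p = 6.82e-07 by the exact test). That rule assigns more sequence to a gene whose start lies far from other starts. Genes were not matched for this, so the 10.6 and the pan-neuronal 8.12 may partly reflect the spacing of genes. Neither body wall muscle genes (3 of 30, odds ratio 2.01, adjusted p = 0.295, with *unc-60* at 2.88 ± 0.444 and *act-4* at 2.87 ± 1.80, from 1.6 in replicate 3 and 4.15 in replicate 4) nor aminoacyl-tRNA synthetase genes (3 of 31, 1.93, 0.295, with *ears-2* at 4.87 ± 0.343 and *mars-1* at 2.17 ± 0.286) passed the exact test. The same was true of intestinal genes (1 of 29, odds ratio 0.643, adjusted p = 1.00 by the exact test, *erm-1* at 2.59 ± 0.570) and of vulval, Notch and Wnt genes (1 of 30, 0.621, 1.00, *egl-17* at 2.22 ± 0.446). Homeobox genes (2 of 90, odds ratio 0.408, adjusted p = 0.395 by the exact test, *ceh-38* at 4.89 ± 0.199 and *ceh-39* at 3.24 ± 0.119) and nuclear hormone receptor genes (9 of 274, 0.609, 0.263, with *nhr-68* at 8.09 ± 0.569 and *nhr-47* at 6.81 ± 0.0221) did not pass either. None of 37 germline genes was bound, which allows a share of up to 9.49% (adjusted p = 0.329 by the exact test). The direction turned with the nearest start for aminoacyl-tRNA synthetase (0.788), intestinal (1.83), vulval (2.86) and nuclear hormone receptor genes (1.25).

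Because *lsy-12* acts in the ASE neurons, genes of ASE asymmetry and gustatory function were examined one by one. Of 23, *lsy-2*, a zinc finger gene of the same pathway (X:2089704–2093256), was the only one bound, which gave an odds ratio of 0.819 (95% interval 0.0198 to 5.08, adjusted p = 1.00 by Fisher's exact test). Its summit lay 40 bp upstream of the start and ranked 2001 among thresholded peaks, with a relative signal of 1.5 in replicate 3 and no overlapping region in replicate 4. None of the 23 was bound with either replicate alone or with the peaks of above-median signal. Candidate regions below the threshold lay in the windows of *unc-37*, the Groucho homolog (1.56 ± 0.234, n = 2), *flp-6* (1.16 ± 0.0830), *fozi-1* (1.10 ± 0.366) and *ceh-37* (1.04 ± 0.0513). The windows of *die-1* and *lsy-27* held a candidate region in replicate 4 but not in replicate 3, with 0.765 and 0.855. No candidate summit was listed in the windows of *che-1*, *cog-1*, *ceh-36*, *ceh-23*, *lim-6*, *hen-1*, *gcy-5*, *gcy-6*, *gcy-7*, *gcy-14*, *gcy-22*, *flp-4*, *flp-20*, *tax-2*, *tax-4* and *osm-3*. Values from whole animals do not show that LSY-12 is absent from these genes in single neurons.

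Genes on chromosomes I and III were bound more often, and genes on V and X less often, than genes on the other chromosomes. The share was 7.23% on I (odds ratio 1.5, adjusted p = 2.00e-06) and 7.69% on III (1.62, 3.77e-08), against 3.68% on V (0.623, 2.01e-08) and 4.25% on X (0.775, 0.0166), by two-sided Fisher's exact tests. Chromosomes II (5.07%, adjusted p = 0.615) and IV (5.00%, adjusted p = 0.592) did not differ from the rest by the exact test. Per Mb, X nonetheless held 23.4 peaks, close to chromosome I with 23, and 26.1% of its summits lay in promoters.

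Short non-coding RNA genes were frequent places of LSY-12 peaks. Of 612 tRNA genes, 209 (34.2%) had a summit within 500 bp of the start, against 5.26% of protein-coding genes (odds ratio 9.34, 95% interval 7.78 to 11.2, adjusted p = 3.96e-101 by Fisher's exact test). The snoRNA genes followed with 93 of 346 (26.9%, 6.62, 1.12e-37), then snRNA genes with 23 of 129 (17.8%, 3.91, 4.40e-07) and miRNA precursors with 27 of 261 (10.3%, 2.08, 0.00134), by the same exact test. The lincRNA and other ncRNA class had 584 of 7958 (7.34%, odds ratio 1.43, adjusted p = 1.08e-10), and pseudogenes had 14 of 2128 (0.658%, 0.119, 6.28e-30 by the exact test). None of 20 rRNA genes had a summit (adjusted p = 0.623 by the exact test), and 2 of the 20 had a mostly single-copy window. More than 1000 bp from every protein-coding start, tRNA genes had an odds ratio of 8.60, that of snRNA genes was 2.57, and that of lincRNA and other ncRNA was 1.06 and no longer passed (adjusted p = 0.463 by the exact test). The miRNA call was lost with the peaks of above-median signal (odds ratio 1.00, adjusted p = 1.00 by the exact test), and snRNA genes with mostly single-copy windows had an odds ratio of 7.08.

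**Figure D4:**
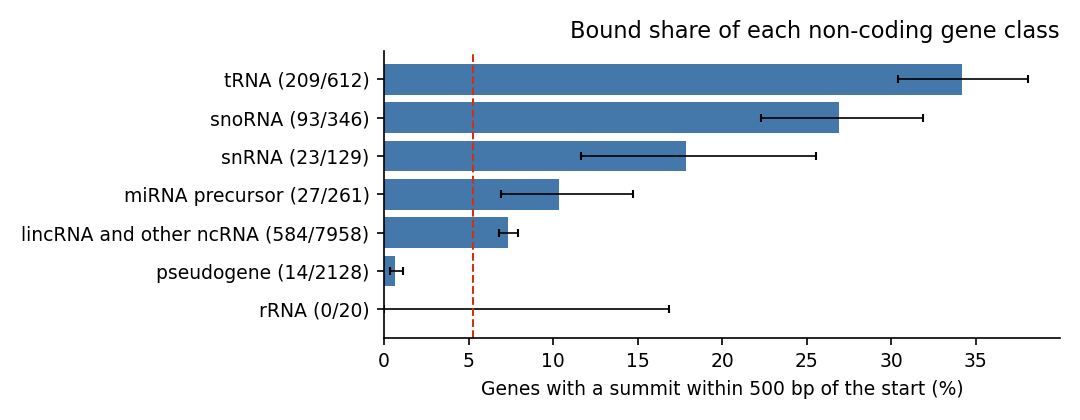
Percent of genes of each non-coding class with a summit within 500 bp of the start, with exact 95% intervals. The dashed line marks protein-coding genes (5.26%), and tRNA genes have the highest share (34.2%).

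The *lsy-12* locus (WBGene00045419, V:9846157–9859963, minus strand) was examined because the strain carries an integrated transgene of this gene, so reads from the transgene also map there. Within 20 kb of the start lay 4 thresholded peaks, more than in 96.0% of such windows around protein-coding genes. They lay 103 bp downstream of the start, inside the gene (1.91 ± 1.20, n = 2), and upstream of it at −543 bp (4.28 ± 0.384), −2894 bp (2.37 ± 0.0462) and −5306 bp (3.23 ± 1.79). The peak at the start ranked 1859 of 2095, with 2.75 in replicate 3 and 1.06 in replicate 4 and an authors' −log10 q-value of 1.36. The peak at −5306 bp had 4.50 in replicate 3 and 1.97 in replicate 4, and with replicate 4 alone the window held 3 peaks. The highest signal there, of the peak at −543 bp (rank 436 of 2095), was above that of 84.3% of the windows. Windows without a peak counted as 0 and the median window held 0 peaks, so much of this percentile reflects only that a peak is present. It describes the locus without a test.

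**Figure D5:**
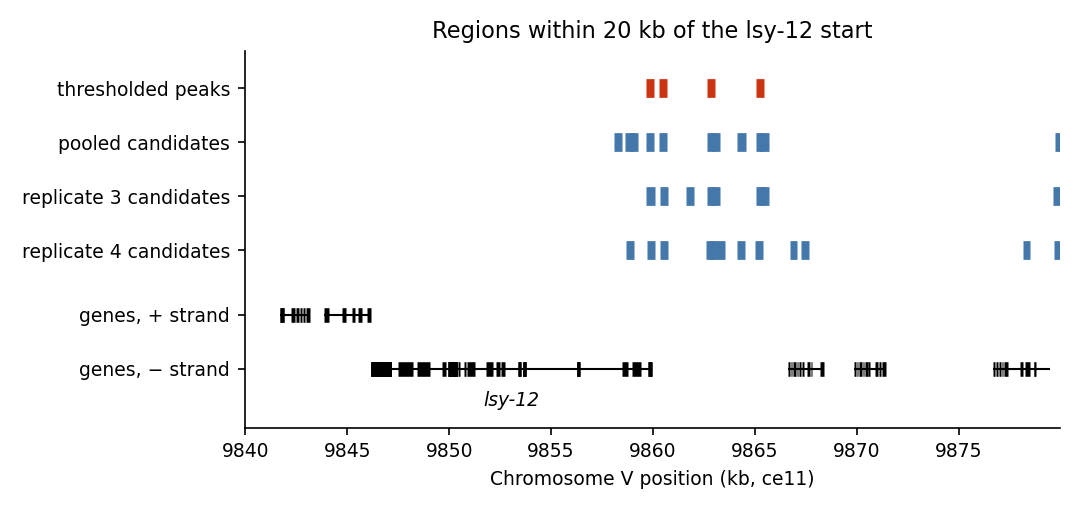
Map of 20 kb to either side of the *lsy-12* start on chromosome V (ce11, position in kb), with genes and the candidate regions of each list. The 4 thresholded peaks lie at and upstream of the start.

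Summit sequences were richer in GC and held particular hexamers more often than sequence 300 bp away. Median GC content was 47.5% at summits against 34.7% in the flanks. The hexamer ACGCAG occurred in 15% of summit windows and 2.29% of flanking windows (6.56-fold, adjusted p = 1.16e-74), GACGCA in 14% against 2.34%, CGTCTC in 15.4% against 3.34%, GAGAGA in 22.5% against 7.47% and AGAGAG in 19.6% against 5.82%, by Fisher's exact test. Less frequent were AAAATT (16.3% against 40.4%), AAAAAT (22.9% against 46.8%), TTAAAA (8.21% against 26.4%), AAAAAA (20% against 40.8%) and ATTTTA (7.40% against 23.5%). In all, 749 of 2080 hexamers were more frequent and 506 less frequent. Genome windows of the same GC count, chosen after the data were seen, were taken outside the pooled candidate regions. They were not matched for position in genes, so differences from them may reflect more than binding. Against them 380 hexamers were more frequent, of which 296 were also more frequent against the flanks, and 418 were less frequent. There AAAAAT (1.06-fold) and TTAAAA (1.05-fold) turned in direction and no longer passed (adjusted p = 0.344 and 0.734 by the exact test). AAAAAA turned and passed as more frequent (1.23-fold, adjusted p = 0.00141 by the exact test). ATTTTA no longer passed (0.878-fold, adjusted p = 0.282 by the exact test), and AAAATT had 0.865-fold. Enrichment was 3.68-fold for ACGCAG, 3.79-fold for GACGCA and 2.67-fold for CGTCTC, where comparison with the flanks gave 6.56, 6.0 and 4.6-fold. It was 2.84-fold for GAGAGA and 2.88-fold for AGAGAG, where the flanks gave 3.02 and 3.37-fold.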

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

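The single-copy backgrounds, the GC-matched windows and the list without *lsy-12* were chosen after the results were seen, and the other alternatives before. Of 293 alternative values with a test, 260 kept their direction and their side of the threshold. The other 187 have no test, and with 2 replicates a single gene's mean signal always stays within 1 SD when a replicate is left out, which says nothing about stability. Replicate overlap ranged from 64.4 to 77%, promoter enrichment from 2.02 to 2.46-fold, and the odds ratio of ribosomal protein genes from 7.35 to 30.5 and of tRNA genes from 6.71 to 10.3. Genes on chromosomes I, III, V and X kept their calls in each alternative run. Replicate overlap needs both lists, so neither replicate could be left out there. No paired analysis was possible because the labels give a single group.

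With the peaks of above-median signal, untranslated exons passed (0.579-fold), bound genes numbered 611 and lists passing 6 of the former 11, where fewer peaks were used. The proteasome (4.39), histone (2.58), heat shock (4.77), collagen (0.184) and miRNA (1.00) calls were lost, and no pan-neuronal gene was bound (odds ratio 0). With 1000 bp upstream and 100 bp downstream, sequence between genes turned (0.960-fold), as did intestinal (1.12) and vulval genes (1.08), and collagen lost its call (0.356). With every transcript start, untranslated exons passed (0.574-fold). With the nearest start, 1607 genes were bound, 840 of them shared with the 1050, and histone (1.27) and collagen genes (0.555) lost their calls. There epidermal regulators passed (10.6), and aminoacyl-tRNA synthetase (0.788), intestinal (1.83), vulval (2.86) and nuclear hormone receptor genes (1.25) turned. Genes were not matched for distance to other starts in that setting. Collagen also lost its call with mostly single-copy windows (0.251), pan-neuronal genes with shifts along gene order (3.29-fold), and lincRNA and other ncRNA far from protein-coding starts (1.06). Against GC-matched windows 380 hexamers were more frequent, 296 of them shared with the 749. AAAAAT (1.06) and TTAAAA (1.05) turned without passing, and AAAAAA (1.23) turned and passed as more frequent. ATTTTA lost its call (0.878), and ACGCAG fell from 6.56 to 3.68-fold and CGTCTC from 4.6 to 2.67-fold. With a single replicate, values ranged from 0.792 to 1.08 for untranslated exons, 0.225 to 0.323 for collagen, 1.36 to 1.43 for intestinal, 2.94 to 4.02 for pan-neuronal, 0.663 to 1.31 for vulval and 1.85 to 2.63 for histone genes. Beyond the smaller number of peaks and the change of window or background, the cause was not tested. Lists of 23 to 40 genes limit what can be detected, and read depth is unknown.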

Other observations

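The tests on gene name families, on the strength of ribosomal peaks, on the X chromosome, on tRNA genes by cluster, copy and GC content, and on intervals without regions were chosen after the results were seen, and the 3 tests on ribosomal protein genes before.

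Other gene families with frequent LSY-12 peaks were sought among the 175 families of gene names with at least 10 members, and 12 passed, 9 of them higher and 3 lower. Beyond the groups already described, the *sec* genes of protein translocation and secretion had 6 of 19 bound (odds ratio 8.36, adjusted p = 0.00860 by Fisher's exact test, two-sided), including *sec-61.A*, *sec-61.B* and *sec-61.G*. The *dnj* genes of DnaJ chaperones had 7 of 29 (5.76, 0.0116), the *cyn* genes of cyclophilins 5 of 16 (8.22, 0.0156) and the *lin* genes 9 of 47 (4.30, 0.0116), by the same exact test. The *lin* genes share only a name, and *lin-53*, *lin-28* and *lin-14* among the 9 belong to lists already described. C-type lectin genes had 2 of 240 (0.150, 0.00860 by the exact test). These families and the *sec-61* genes were named after their values were seen.

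Among the epidermal and heterochronic regulators, peaks whose nearest start was theirs lay at −1447 bp from the start of *lin-41* (3.91 ± 0.0721, n = 2), −1682 bp for *blmp-1* (2.64 ± 0.239), −1056 bp for *hbl-1* (2.1 ± 0.616) and 2784 bp for *nhr-23* (2.55 ± 0.0846), and a further peak 903 bp downstream of the *lin-28* start (3.69 ± 1.01). These genes were chosen after their values were seen. On X, 75 of 414 summits (18.1%) lay near a tRNA gene and no protein-coding start, against 73 of 1681 (4.34%) on the autosomes (odds ratio 4.87, adjusted p = 6.11e-18 by Fisher's exact test). X carried 276 tRNA genes and all autosomes together 336. The share of tRNA genes with a summit was 36.2% on X and 32.4% on the autosomes (odds ratio 1.18, 95% interval 0.834 to 1.68, exact p = 0.347). The larger share of such summits on X thus goes with the number of tRNA genes there.

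Ribosomal protein genes were bound often (odds ratio 24.2), and their 42 promoter peaks were stronger than 786 others (median relative signal 5.45 against 3.26, two-sided permutation p = 2e-05, the smallest that 100000 permutations can give). This strength test was chosen after ribosomal promoters were seen among the strongest peaks, so its p restates that observation. GC content within 500 bp of the start argues against base composition at that scale as the whole cause. The odds ratio within its deciles was 14.2 (95% interval 9.02 to 22.4), though lower than without them. GC content at the summit itself was not matched, so local base composition stays open. Summits that belong to a neighbour with a shared promoter cannot be told apart from binding to the ribosomal gene for 28 of the 45. With genes that share a summit called unbound but kept in the counts, 17 of 80 ribosomal protein genes were bound, against 2.98% of other genes. The odds ratio was then 8.79 (4.79 to 15.3), with its lower end just short of the bound of 5 set beforehand. That rule counts any binding at a shared promoter as absent, which can lower the ratio. Non-specific signal at strongly transcribed genes stays open, since tRNA genes far from protein-coding starts, which RNA polymerase III transcribes, also had an odds ratio of 8.60 (6.91 to 10.7). Neither animals without the tag nor expression values were analysed here, so a role of LSY-12 at these genes is untested.

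The tRNA genes had a summit in 34.2% of cases. Counting each group of neighbours once left an odds ratio of 9.61 (7.84 to 11.8), which argues against clusters as the cause. For tRNA genes whose sequence occurs once it was 5.84 (3.85 to 8.67), and within deciles of GC content 6.89 (5.73 to 8.27). Identical copies and GC content within 500 bp of the start may thus add to the pattern but do not account for all of it. Base composition at the summit itself was not matched here either and stays open. Among tRNA genes with a mostly single-copy window, 163 of 431 had a summit (37.8%, odds ratio 10.3, 8.32 to 12.7). Repeated sequence around the genes is thus argued against, although such a window can still hold a short identical copy. Non-specific signal stays open here too, and no biological explanation was tested.

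The longest interval with no region in any list was V:2346258–2564427, 218170 bp with 48 protein-coding genes. Of its 32-mers, 99.4% occur more than once in the reference, against 8.55% of the genome, so a candidate explanation is that reads from repeated sequence were not kept. A lack of genes is argued against by 220 protein-coding starts per Mb there, against 199 in the genome. Of the 18 such intervals over 50000 bp, 4 were mostly repeated sequence, and 13 lay on chromosome IV between 14520945 and 16919133 with medians of 15.8% repeated and 118 protein-coding starts per Mb, so repeats leave most of these open and few genes are not argued against there.

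A stretch of 61422 bp without a pooled summit (V:9796857–9858279) covered most of the *lsy-12* gene but not its 5' end, where pooled candidate regions lay, and 20 of 29994 distances between pooled summits were as long. In replicate 3 the distance between the summits on either side was 21667 bp (337 as long) and in replicate 4 it was 19188 bp (454 as long). The pooled interval had 3.90% repeated 32-mers.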
